A study of Mus musculus with 8 samples.

How the data were processed

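RNA sequencing libraries from isolated islets of 1-year-old C57BL/6 mice were analysed for 2 genotypes, Flox/Flox and β-Tead1-KO. Per the labels' protocols, islets were freed with collagenase, purified on a density gradient, picked by hand and frozen, and libraries were made with an Illumina TruSeq RNA kit from column-purified RNA. The 8 samples are 4 libraries run on 2 lanes each: the labels give library numbers 1 and 2 in each genotype and name the lane of each sample. Per the series' design text each library pools 3 samples, while the sample descriptions carry 1 or 2 numbers per library that look like animal numbers, so the size of the pools is unclear. The library was taken as the replicate, 2 per genotype.

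Each lane has its own table of 48709 Ensembl genes. The deposited tables hold whole-number read counts per gene, split into exon, exon-exon junction and intron reads and into unique and total reads, per the file headers. They also hold TPM and RPKM, the authors' own normalised values per the file headers. In each table RPKM, exon length and total exon reads gave 1 constant total, so RPKM was made from total exon reads; TPM and RPKM were not used for tests. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. Gene names and positions were taken from the files.

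Total exon reads of the 2 lanes of a library were summed. Exon reads totalled 14069569 to 26387280 per library and 6940492 to 13398623 per lane. Counting intervals are exact 95% binomial intervals and cover counting error only, since the reads carry no molecular identifiers. The 2 lanes of each library were compared by a chi-square test of exon counts over genes with a mean count of at least 10, scaled by lane totals. The statistic over its degrees of freedom, which is 1 under sampling noise alone, was 1.20 and 1.16 for Flox libraries 1 and 2 and 1.07 and 1.17 for β-Tead1-KO libraries 1 and 2. Between the 2 libraries of a genotype it was 66.8 in Flox and 48.4 in β-Tead1-KO. Lanes thus differed a little more than sampling noise, by far less than libraries, and were counted as 1 replicate.

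Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 15014 genes, and scaled with TMM factors. Genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are libraries labelled β-Tead1-KO over Flox, and standard errors were obtained from the fold change and the F statistic. Intron and junction levels were scaled and tested the same way on their own reads. Levels are TMM-scaled CPM (exon reads scaled to a common library total). The estimated biological coefficient of variation was 24.3%.

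A set of 28 gene lists was fixed before the data were examined: β-cell identity, β-cell function, disallowed or immature genes, cell cycle, cell cycle inhibitors and senescence, Hippo components, YAP/TEAD targets, unfolded protein response, nuclear oxidative phosphorylation, glycolysis, interferon and MHC, α-cell, δ-cell, polypeptide and ε-cell, acinar, ductal, endothelial, mesenchymal, macrophage, lymphocyte, neural and Schwann cell, erythroid, adipocyte, lymph node stroma, immediate early and dissociation, sex-linked, mitochondrially encoded, and extracellular matrix. Of 518 entries 515 were matched to a gene of the files by symbol or older symbol, and 483 were tested. The 26 lists with at least 3 tested members, the sex-linked list left out, were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01 and adjusted over the 26 lists. With an estimated correlation 0 lists passed, and 0 had an unadjusted p below 0.05. That version takes its p from the 2 residual degrees of freedom of the fit, which raises p even where the estimate is low. For β-cell function the estimate was -0.026, below the preset 0.01, yet camera's unadjusted p went from 0.000207 to 0.0523. A miss with an estimated correlation therefore does not show that members moving together made a call. Camera with an estimated correlation and each library left out in turn was added after the data were seen; with 1 residual degree of freedom the lowest unadjusted p was 0.124, so it decides nothing and is not used. The 95% t intervals of list means per library were added after the data were seen too. With limma-voom as the input and the preset correlation, camera called 12 lists. Some genes belong to several lists.

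Named genes followed a rule fixed at the same time. Tead1 came first. A core set followed whatever its result: Ins1, Ins2, Pdx1, Mafa, Nkx6-1, Slc2a2, Ucn3, Glp1r, Cdkn2a, Mki67, Cyr61, Ctgf, Gcg and Sst. Next came the 10 largest fold changes in each direction among genes past the threshold with a mean CPM of at least 5 and both libraries labelled β-Tead1-KO on the same side of both Flox libraries, leaving out provisional gene models and pseudogenes. Some genes that the rule takes are not reported here. Up to 4 members per list with the smallest unadjusted p and a mean CPM of at least 1 closed the rule. Ffar1, Pcsk1 and Fos, and the genes of the closing paragraphs that fall outside it, were named after their values were seen.

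The edgeR, camera and lane tests were first tested on simulated data drawn from the real means and library sizes, with 200 genes changed. For the comparison of 2 against 2 libraries over 14980 genes, 93.9% of genes changed 4-fold and 19.6% of genes changed 2-fold were called in the right direction, with 5 false calls among 116. A list raised 2-fold ranked 1 of 26 in camera over 15001 genes, and with no list changed 0 were called. The genes were drawn independently of each other and at a common dispersion. The simulation therefore cannot show how camera with the preset correlation behaves where members move together. In the real data the estimated correlation was 0.51 for the cell cycle list, 0.97 for the erythroid list and 0.98 for the acinar list, which was not called. Among the other called lists it was 0.60 for polypeptide and ε-cell, 0.21 for δ-cell, 0.18 for mesenchymal, 0.15 for α-cell and 0.053 for Hippo components. It was below 0 for β-cell function (-0.026), YAP/TEAD targets (-0.032), disallowed or immature genes (-0.036), extracellular matrix (-0.039) and endothelial markers (-0.068). Poisson lanes gave a lane statistic of 1.01 over 13535 genes.

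Alternatives fixed in advance were DESeq2 size factors, upper quartile factors, TMM with the acinar list and the 20 most abundant genes left out, no filter, a CPM of at least 1 in every library, the Wald test of DESeq2 1.42.0, edgeR's legacy mode, limma-voom, each lane as its own sample, each lane alone, the library number as a block, other thresholds, each library left out in turn, and for lists an estimated correlation and no shared members. Unique exon reads, exon-exon junction reads and intron share as a covariate were added after the data were seen. Genes whose reads are shared with near-identical copies are given with their percent of unique exon reads; 62 of the called genes had less than 80%. Reads of overlapping or antisense genes cannot be told apart where strand is not known.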

Results

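RNA from isolated pancreatic islets of 1-year-old C57BL/6 mice was sequenced for 2 genotypes. Tead1 encodes a DNA-binding partner of the Hippo pathway coactivators YAP and TAZ. Flox/Flox islets served as the control, and β-Tead1-KO islets, in which the labels place a loss of Tead1 in the insulin-producing β-cells, were the other group. Each genotype had 2 libraries, and each library had been run on 2 sequencing lanes. Per the series' design text, 3 samples had been pooled for each library, while the sample descriptions carry 1 or 2 numbers per library that look like animal numbers, so the size of the pools is unclear. Exon reads totalled 21938244 and 14069569 in Flox libraries 1 and 2, and 22352518 and 26387280 in β-Tead1-KO libraries 1 and 2. Insulin transcripts (Ins1 and Ins2 together) took 18.3% and 20.4% of exon reads in the Flox libraries, and 17.0% and 15.2% in the libraries labelled β-Tead1-KO. The comparison asks which islet genes differ at 1 year of age between the genotypes. With 2 libraries per genotype, the p-values rest on the spread between these libraries and on a variance estimate shared across genes. They cover no spread beyond these libraries.

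Tead1 itself was not lower in the libraries labelled β-Tead1-KO. The gene (ENSMUSG00000055320, mm10 chromosome 7, 112679318 to 112906807, plus strand) had 101 and 124 CPM (TMM-scaled exon reads) in the Flox libraries. It had 137 and 163 CPM in the libraries labelled β-Tead1-KO. The log2 fold change was 0.41 with a standard error of 0.19, and it did not pass the test (edgeR adjusted p = 0.347, n = 2 per genotype). Reads crossing an exon-exon junction made up 12.8% (95% exact binomial interval 11.5 to 14.3) and 12.5% (11.0 to 14.1) of Tead1 exon reads in Flox. The share was 10.1% (9.09 to 11.3) and 10.2% (9.32 to 11.1) in the libraries labelled β-Tead1-KO. On junction reads alone the log2 fold change was 0.10 (edgeR adjusted p = 0.850), a read class chosen after the data were seen. Gene-level reads sum all exons and cannot resolve a deleted exon, and islets hold other cells besides β-cells, so the Tead1 total does not check the labels. The direction of every difference given here rests on those labels.

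**Figure D1:**
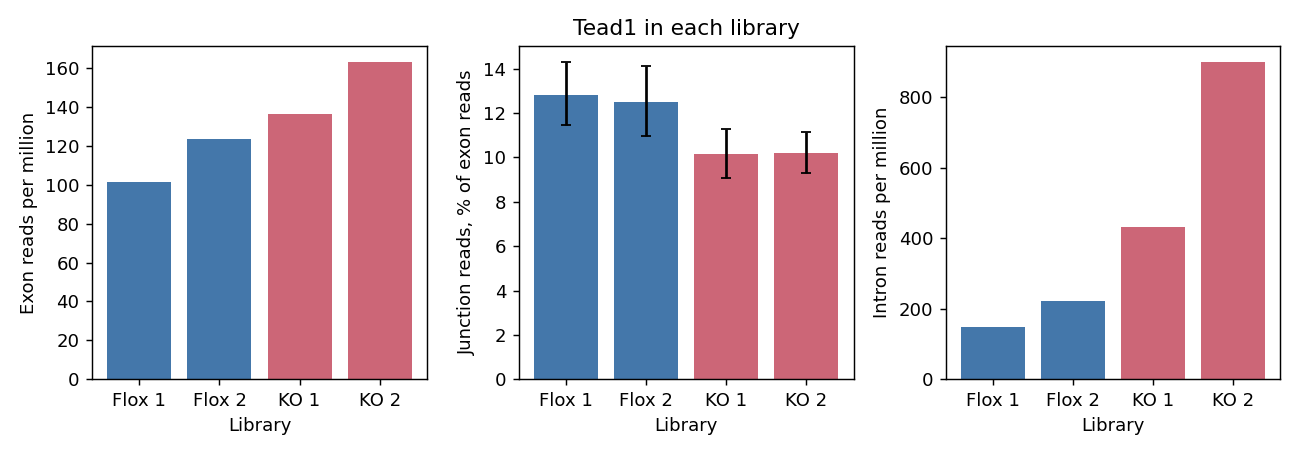
Tead1 in each of the 4 libraries: exon reads in CPM (left), reads crossing an exon-exon junction as a percent of Tead1 exon reads with 95% exact binomial intervals (middle), and intron reads in CPM (right). Blue bars are Flox and red bars are the libraries labelled β-Tead1-KO (KO in the axis labels): exon reads were 101 and 124 in Flox against 137 and 163, and intron reads were 149 and 223 against 431 and 900.3.

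Between the libraries labelled β-Tead1-KO and Flox, 504 of 15014 tested genes changed, 264 higher and 240 lower (edgeR, adjusted p below 0.05). Of these, 481 differed by at least 2-fold, and 482 were protein-coding. The 10 genes with the largest rises that met the naming rule were the long noncoding RNA RP23-57D10.2, C4bp, Crabp1, Edil3, Iqsec3, Aldh1a3, Tnfrsf19, Bmp2, Gulp1 and Plet1. Aldh1a3, a retinaldehyde dehydrogenase that is scarce in healthy β-cells, was at 8.93 ± 5.04 CPM (SD, n = 2) in Flox. In the libraries labelled β-Tead1-KO it reached 651 ± 169 CPM (SD, n = 2), a log2 fold change of 6.18 (SE 0.51, edgeR adjusted p = 0.00615). Edil3, an extracellular matrix protein, went from 3.37 to 279 CPM on average (log2 fold change 6.36, SE 0.33). C4bp, a complement regulator, had 9 reads over both Flox libraries and 6566 over the other 2, a ratio of 532 with an exact 95% counting interval of 280.2 to 1164. RP23-57D10.2 had 2 Flox reads against 2435, a ratio of 888 (245.6 to 7337). Crabp1, a retinoic acid binding protein, had 1 Flox read against 500, a ratio of 365 (65.2 to 14434). Tnfrsf19 had 6 Flox reads, all in library 1, against 584, a ratio of 71.0 (32.4 to 194). Its log2 fold change was 6.14 and ranged from 5.39 to 10.97 with a library left out. Iqsec3, the growth factor Bmp2 and Gulp1 had log2 fold changes of 6.28, 5.78 and 5.61. Plet1 rose by 5.35 on the log2 scale, but only 46% of its exon reads mapped uniquely, so its level is uncertain.

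The 10 genes with the largest falls under the same rule were Msln, Mlph, Cdh7, Aqp4, Adgrl3, Cnnm1, Reln, St8sia5, Rasd2 and Angptl7. Mesothelin (Msln) went from 18.4 ± 14.7 CPM (SD, n = 2) in Flox to 0.101 ± 0.0162 CPM (SD, n = 2), a log2 fold change of -7.40 (SE 0.86, edgeR adjusted p = 0.0153). Mlph, which links secretory and pigment granules to myosin, went from 22.5 to 0.221 CPM (log2 fold change -6.61, SE 0.45). Cdh7, a cadherin, and Aqp4, a water channel, had log2 fold changes of -6.05 and -5.10. Adgrl3, Cnnm1, the secreted glycoprotein Reln, St8sia5 and Rasd2 ranged from -5.03 to -4.23. Angptl7 had a log2 fold change of -4.09, with 30% of its exon reads mapping uniquely. With limma-voom Msln and Rasd2 missed the threshold (adjusted p = 0.155 and 0.0791).

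The count depended strongly on single libraries and on the tool. It was 2359 without Flox library 1, 964 without Flox library 2, 89 without β-Tead1-KO library 1 and 67 without β-Tead1-KO library 2, where the lone library of an arm was assumed to vary like the others; DESeq2 called 1117. Of the 52 called genes named in the text, 20 still passed without β-Tead1-KO library 1, 19 without β-Tead1-KO library 2 and 52 with either Flox library left out. The first principal component held 61.1% of the variance and separated the genotypes, and the second held 29.1% and separated library 1 from library 2 in both genotypes.

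Genes of β-cell function were lower as a group. The camera test placed the list below other genes (29 members, median log2 fold change -0.47, adjusted p = 0.00108; adjusted p = 0.421 with an estimated correlation). Slc2a2, the main glucose transporter of mouse β-cells, went from 925 ± 120.2 to 187 ± 43.8 CPM (SD, n = 2 each), a log2 fold change of -2.30 (SE 0.26, edgeR adjusted p = 0.0138); 43% of its reads mapped uniquely. Trpm5, a cation channel that takes part in glucose-induced electrical activity, fell by 3.07 on the log2 scale (SE 0.42). The granule protein Sytl4, the fatty acid receptor Ffar1 and the prohormone convertase Pcsk1 had log2 fold changes of -1.43, -1.34 and -1.07; Pcsk1 missed the threshold with no filter (adjusted p = 0.0651) and in edgeR's legacy mode (0.0508). Adcy8, an adenylate cyclase, went the other way, from 0.502 to 15.7 CPM (log2 fold change 4.94, SE 0.27; 68% unique reads). In all, 6 of the 29 members passed in edgeR over all genes, 5 lower and 1 higher, and 11 passed when adjusted over the list alone, 10 of them lower. DESeq2 called 13 members, 11 lower and 2 higher. With a library left out the list's median ranged from -0.55 to -0.31. In the same libraries the median log2 fold change was -1.26 for δ-cell, -1.57 for polypeptide and ε-cell, 0.79 for mesenchymal and 1.58 for erythroid markers (adjusted p = 0.421, 0.561, 0.515 and 0.561 with an estimated correlation).

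No gene of the β-cell identity list passed over all 15014 genes or when adjusted over the list alone (edgeR), and the list's camera test missed the threshold (20 members, median log2 fold change -0.22, adjusted p = 0.0758; 0.561 with an estimated correlation). At an unadjusted p below 0.05, 5 of its members differed; DESeq2 called 4 members, all lower, and limma-voom called 0. The list passed camera with DESeq2's statistics (adjusted p = 0.0255). Without Flox library 2 its median log2 fold change was -0.21. Pdx1, a transcription factor of β-cell identity, was at 206 ± 19.7 CPM in Flox and 118 ± 6.31 CPM in the libraries labelled β-Tead1-KO (SD, n = 2 each; log2 fold change -0.80, SE 0.16, edgeR adjusted p = 0.0663). Mafa was at 47.6 and 184 CPM in the Flox libraries and at 26.1 and 29.1 CPM in the others (log2 fold change -2.07, SE 0.59, adjusted p = 0.153). Nkx6-1 had a log2 fold change of -0.60 (edgeR adjusted p = 0.194). Among core genes outside this list, the maturity marker Ucn3 had a log2 fold change of -0.93 (adjusted p = 0.103). For Glp1r, the receptor for the incretin GLP-1, it was -1.18 (adjusted p = 0.0617). Without Flox library 1 or 2, the log2 fold changes were -0.89 and -0.70 for Pdx1 and -2.72 and -0.79 for Mafa. They were -0.89 and -0.95 for Ucn3 and -1.41 and -0.88 for Glp1r. Such fits take the spread between libraries from the β-Tead1-KO pair alone, so whether a gene passed in them decides nothing. DESeq2 called Pdx1, Nkx6-1, Ucn3 and Glp1r (adjusted p = 0.000803, 0.0311, 0.0014 and 0.000184). Pdx1 also passed on junction reads (0.0404) and Glp1r on unique reads (0.0476), and with intron share as a covariate Pdx1, Mafa, Ucn3 and Glp1r passed (0.0245, 0.0461, 0.0327 and 0.0339).

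Of the 2 mouse insulin genes, neither passed the test. Ins1 was at 60371 ± 4229.9 CPM in Flox and 29360.3 ± 348 CPM in the libraries labelled β-Tead1-KO (SD, n = 2 each), and Ins2 at 134031 ± 6578 and 131280 ± 13321 CPM. Ins1 had a log2 fold change of -1.04 with a standard error of 1.16 in edgeR (adjusted p = 0.722). DESeq2 gave the same fold change a standard error of 0.17 and an adjusted p of 9.87e-08. The edgeR error was thus not set by the spread between libraries alone, since edgeR also draws on the variance of other genes. For Ins2 the log2 fold change was -0.03 (SE 2.04, adjusted p = 0.996).

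**Figure D2:**
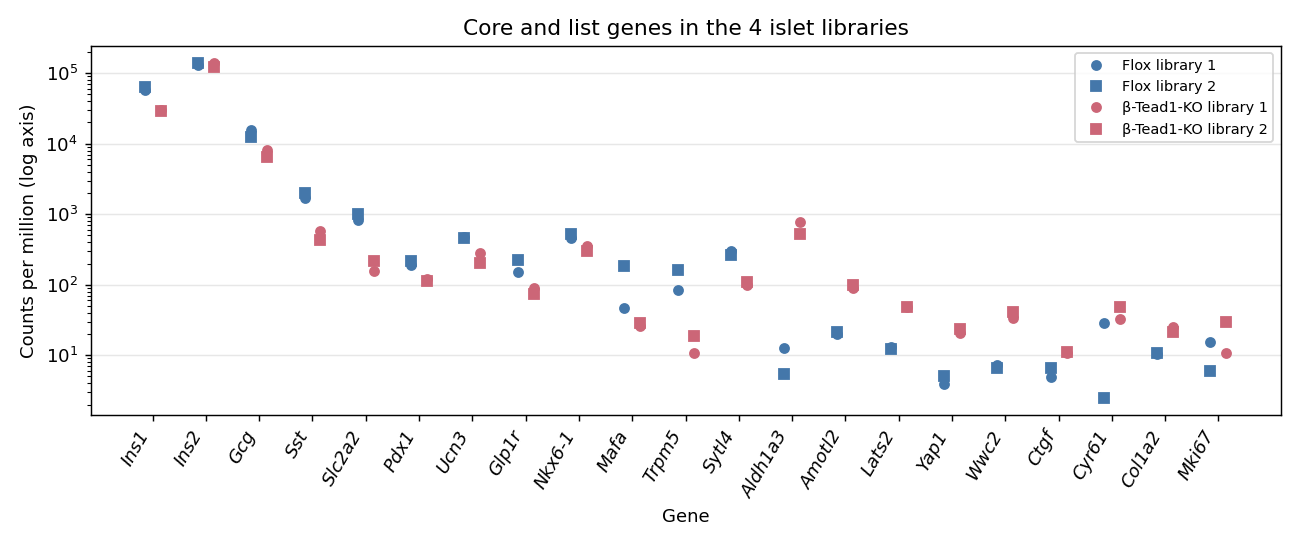
CPM on a log axis for core genes and members of the gene lists in the 4 libraries; circles are library 1, squares library 2, blue Flox and red the libraries labelled β-Tead1-KO. Slc2a2 averaged 925 against 187, Aldh1a3 8.93 against 651 and Ins1 60371 against 29360.3, while the Mafa points of the Flox libraries lie far apart at 47.6 and 184.

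Genes that mature β-cells normally keep silent, or that mark immature β-cells, were higher as a group (16 members, median log2 fold change 0.51, camera adjusted p = 0.000681; adjusted p = 0.421 with an estimated correlation). Besides Aldh1a3, the transcriptional repressor Rest rose from 4.03 to 21.0 CPM (log2 fold change 2.37, SE 0.24), the lactate and pyruvate transporter Slc16a1 from 1.20 to 5.32 CPM (2.14, SE 0.30), the tetraspanin Cd81 from 79.0 to 190.2 CPM (1.27, SE 0.17) and the low-Km hexokinase Hk1 from 8.02 to 17.7 CPM (1.14, SE 0.19). These 5 members passed over all genes, all higher, and 6 passed adjusted over the list alone, all higher. On junction reads Slc16a1 missed the threshold (edgeR adjusted p = 0.133), and on lane 2 alone Slc16a1 and Hk1 missed it (adjusted p = 0.0570 and 0.0596). In the same libraries the median log2 fold change of the mesenchymal list was 0.79 and that of the erythroid list 1.58 (adjusted p = 0.515 and 0.561 with an estimated correlation). The list shares members with the mesenchymal list: Pdgfra, chosen here after its value was seen, was the sixth to pass over the list alone (log2 fold change 1.82), and Pdgfrb had a log2 fold change of 0.40. Without members shared with any other list, the list passed camera with the preset correlation.

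Markers of the other islet endocrine cells were lower. Somatostatin (Sst), the δ-cell hormone, went from 1838 ± 213 to 502 ± 104 CPM (SD, n = 2 each; log2 fold change -1.87, SE 0.28, edgeR adjusted p = 0.0294), and Fam159b from 8.78 to 1.91 CPM (log2 fold change -2.21, adjusted p = 0.0390; -1.69 and adjusted p = 0.0737 on junction reads). All 6 δ-cell members were lower on average, 2 passed over all genes and 6 when adjusted over the list alone (camera adjusted p = 7.61e-05; adjusted p = 0.421 with an estimated correlation). In the α-cell list 1 of 12 members passed over all genes, lower in the libraries labelled β-Tead1-KO; 6 passed adjusted over the list alone, 4 lower and 2 higher (camera adjusted p = 0.0246; adjusted p = 0.561 with an estimated correlation). Glucagon (Gcg) was at 13878 and 7238 CPM on average (log2 fold change -0.94, SE 0.58, edgeR adjusted p = 0.500). DESeq2 gave it a standard error of 0.22 and an adjusted p of 0.000527, and called 5 of the 12 α-cell members. Of the pancreatic polypeptide and ε-cell list, Pyy and Ppy had log2 fold changes of -1.89 (adjusted p = 0.0552) and -1.43 (adjusted p = 0.101); no member of 4 passed in edgeR over all genes, against 3 at an unadjusted p below 0.05, 2 with DESeq2 and 0 with limma-voom. Without Flox library 1 or 2 the log2 fold changes were -1.97 and -1.78 for Pyy and -1.43 and -1.42 for Ppy. In edgeR Pyy passed with a CPM of at least 1 in every library (adjusted p = 0.0466) and on lane 1 alone (0.0395). It also passed on unique reads (0.0372) and on junction reads (0.0366). Both genes passed with intron share as a covariate (0.0293 for Pyy and 0.0402 for Ppy). Of the 4, 3 passed adjusted over the list alone, all lower, and the list passed camera (adjusted p = 0.0242; adjusted p = 0.561 with an estimated correlation). Without Flox library 1 the α-cell and polypeptide lists no longer passed camera (adjusted p = 0.235 and 0.165), and without β-Tead1-KO library 2 the α-cell list did not (adjusted p = 0.0689). The α-cell call was also lost on junction reads (0.172) and without members shared with another list (0.0566), and the polypeptide call with a CPM of at least 1 in every library (0.0824), with lanes as samples (0.153) and on lane 1 alone (0.134).

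Genes of the Hippo pathway and of YAP and TEAD transcription were higher, in libraries where Tead1 exon reads were not lower. Of 26 Hippo pathway components, Amotl2, Wwc2, Lats2 and Yap1 rose and none fell (median log2 fold change 0.23, camera adjusted p = 0.00337; adjusted p = 0.505 with an estimated correlation), and 5 passed adjusted over the list alone, all higher. Of 20 YAP/TEAD target genes, Amotl2, Lats2, Myof and Gadd45a rose and none fell in edgeR over all genes. DESeq2 called 7 members, 5 higher and 2 lower. The list's median log2 fold change was 0.57 (camera adjusted p = 0.00219, and 0.421 with an estimated correlation). Adjusted over the list alone 9 passed in edgeR, 7 higher and 2 lower. Amotl2, an angiomotin that binds YAP and is itself induced by it, went from 20.9 ± 0.893 to 95.4 ± 7.63 CPM (SD, n = 2 each; log2 fold change 2.19, SE 0.16, edgeR adjusted p = 0.00469). The kinase Lats2, which phosphorylates YAP, went from 12.6 to 48.2 CPM (1.93, SE 0.16), Wwc2, an upstream scaffold, from 7.02 to 37.3 CPM (2.41, SE 0.20) and the coactivator Yap1 from 4.43 to 22.2 CPM (2.33, SE 0.23). Among the classical targets, Ctgf had a log2 fold change of 0.93 (edgeR adjusted p = 0.122, and 0.0490 on unique reads), and 1.16 without Flox library 2. Cyr61 was at 28.8 and 2.47 CPM in Flox and at 33.1 and 47.7 CPM in the others (log2 fold change 1.36, SE 0.94, adjusted p = 0.545). With a library left out Cyr61 ranged from 0.49 without Flox library 2 to 4.04 without Flox library 1. Without Flox library 1 the target list just missed the threshold (camera adjusted p = 0.0518). The mesenchymal and erythroid medians in the same libraries were 0.79 and 1.58 (adjusted p = 0.515 and 0.561 with an estimated correlation).

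Of 45 cell cycle genes, 36 were higher on average, yet only E2f2, an E2F transcription factor, rose (4.51 to 12.5 CPM, log2 fold change 1.47, SE 0.23, edgeR adjusted p = 0.0313); 1 passed adjusted over the list alone. On junction reads E2f2 had a log2 fold change of 0.79 and missed the threshold (edgeR adjusted p = 0.367). The list passed camera (adjusted p = 0.00482; adjusted p = 0.867 with an estimated correlation), but not with DESeq2's statistics (adjusted p = 0.0626), without Flox library 2 (adjusted p = 0.555) or without β-Tead1-KO library 2 (adjusted p = 0.379). Beside it stood the mesenchymal and erythroid medians of 0.79 and 1.58 (adjusted p = 0.515 and 0.561 with an estimated correlation). The proliferation marker Mki67 was at 15.5 and 5.92 CPM in Flox and 10.6 and 29.6 CPM in the others, so its libraries overlapped (log2 fold change 0.90, adjusted p = 0.533). With a library left out the log2 fold change of Mki67 ranged from 0.0027 without β-Tead1-KO library 2 to 1.77 without Flox library 1. The median of the 45 cell cycle genes moved likewise, from 0.036 to 0.87 in the same settings, so the size of the rise depended on single libraries. No cell cycle inhibitor or senescence gene passed over all genes in edgeR, 4 passed adjusted over the list alone (3 higher, 1 lower), and the list missed the camera threshold (20 members, camera adjusted p = 0.559). At an unadjusted p below 0.05, 7 of these 20 differed; DESeq2 called 4 and limma-voom called 0. Cdkn2a, which encodes p16 and p19 in mice, had 31 reads over both Flox libraries and 11 over the other 2 (log2 fold change -1.91, SE 0.71, adjusted p = 0.262).

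Markers of non-endocrine cells did not move alike. Mesenchymal (stellate) markers were higher (20 members, median log2 fold change 0.79, camera adjusted p = 0.000342; adjusted p = 0.515 with an estimated correlation), with Mgp (log2 fold change 1.65, SE 0.27), Col1a1 (1.74, SE 0.31) and Col1a2 (1.14, SE 0.19) past the threshold and 10 members past it adjusted over the list alone, 9 higher and 1 lower. Over the same list DESeq2 called 9 members, 8 higher and 1 lower. In edgeR 6 members passed on junction reads and 5 on unique exon reads, all higher. Of the 3 genes named, limma-voom called 1: Mgp and Col1a1 missed the threshold (adjusted p = 0.0559 and 0.0831). Col1a1, at an adjusted p of 0.0496, also missed it with no filter (0.0580), in edgeR's legacy mode (0.0504) and on lane 1 alone (0.0505), and Mgp and Col1a2 on lane 2 alone (0.0675 and 0.0578). Of 22 extracellular matrix and adhesion genes Timp2 rose, from 22.9 to 88.9 CPM, and 3 passed adjusted over the list alone (camera adjusted p = 0.00791; adjusted p = 0.421 with an estimated correlation; adjusted p = 0.0518 without Flox library 1). The 5 tested erythroid genes were all higher on average, with the β-globin gene Hbb-bt at 4.40 and 17.2 CPM (log2 fold change 1.96, SE 0.28); 1 passed over all genes, 5 adjusted over the list alone (camera adjusted p = 0.000419; adjusted p = 0.561 with an estimated correlation). All 14 endothelial markers were higher on average by small amounts (median log2 fold change 0.20, camera adjusted p = 0.0242; adjusted p = 0.481 with an estimated correlation), none passed over all genes or over the list alone in edgeR (2 had an unadjusted p below 0.05; DESeq2 called 1 and limma-voom called 0), and the call was lost with DESeq2's statistics (adjusted p = 0.0717), on lane 1 alone (0.0678), without Flox library 1 (0.0811) and without β-Tead1-KO library 2 (0.0510).

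Several lists differed more between libraries of 1 genotype than between genotypes. The 25 acinar genes summed to 0.260% and 0.948% of normalised reads in Flox libraries 1 and 2, and to 0.134% and 1.08% in β-Tead1-KO libraries 1 and 2 (camera adjusted p = 0.717; the median and mean lay just above 0 and the test pointed down). The 14 lymphocyte markers summed to 255 and 26.6 CPM in Flox and 97.5 and 17.6 CPM in the others (camera adjusted p = 0.402). The 21 immediate early and dissociation genes summed to 8809 CPM in Flox library 1, 971 CPM in Flox library 2, and 7563 and 9125 CPM in the libraries labelled β-Tead1-KO (camera adjusted p = 0.105). Fos, the archetypal immediate early gene, was at 2023, 101, 2090 and 2043 CPM in the same order. The immediate early list passed camera without Flox library 1 (adjusted p = 1.17e-09) and on junction reads (0.0195), the acinar list did so without β-Tead1-KO library 2 (adjusted p = 1.53e-06) and the lymphocyte list without β-Tead1-KO library 1 (adjusted p = 8.25e-05) or Flox library 2 (0.00713) and with intron share as a covariate (0.00544). These passes hold for the preset correlation; with all 4 libraries and an estimated correlation the adjusted p was 0.933, 0.943 and 0.933 in the same order. In the immediate early list the heat shock gene Hspa1b fell (20.7 to 3.60 CPM, log2 fold change -2.52, SE 0.35, 70% unique reads). Adjusted over the list alone 2 members passed in edgeR, both lower. The list's median log2 fold change was 0.41 with all 4 libraries, 2.49 without Flox library 1 and -0.40 without Flox library 2.

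The remaining lists did not pass camera. In edgeR 0 members of the acinar, lymphocyte, unfolded protein response and neural lists passed over all genes, 0 at an unadjusted p below 0.05, and 0 with DESeq2 or limma-voom. Of the oxidative phosphorylation, interferon, macrophage, mitochondrially encoded and lymph node stroma lists, edgeR and limma-voom called 0 members, 2, 4, 2, 1 and 1 had an unadjusted p below 0.05 in edgeR, and DESeq2 called 1, 1, 2, 0 and 0. The adjusted p was 0.717 for the unfolded protein response, 0.477 for nuclear-encoded oxidative phosphorylation, 0.958 for interferon and MHC genes, 0.736 for macrophage markers (1 member passed adjusted over the list alone), 0.849 for neural and Schwann cell markers (the median lay below 0, the mean above, and the test pointed up), 0.126 for mitochondrially encoded genes and 0.280 for lymph node stroma (1 passed adjusted over the list alone). Glycolysis (adjusted p = 0.736) held Hk1 as the 1 member past the threshold over all genes and 3 adjusted over the list alone, 1 higher and 2 lower. Ductal markers (adjusted p = 0.736; the mean lay above 0 and the median below) held Cldn4, a tight junction protein that fell from 48.6 to 18.0 CPM (log2 fold change -1.43, SE 0.21). Nuclear oxidative phosphorylation passed without Flox library 1 or β-Tead1-KO library 2 (adjusted p = 0.0111 and 0.0333), lymph node stroma without Flox library 2 or β-Tead1-KO library 1 (0.0323 and 0.00567) and mitochondrially encoded genes without Flox library 2 (0.00618). These passes too hold for the preset correlation; with all 4 libraries and an estimated correlation the adjusted p was 0.933, 0.867 and 0.867 in the same order. The adipocyte list had 1 tested member and no camera test; edgeR, DESeq2 and limma-voom called 0 of it over all genes, and it had an unadjusted p below 0.05 in edgeR, passing when adjusted over the list alone. The 5 sex-linked genes were kept out of the tests of lists; edgeR, DESeq2 and limma-voom each called 0 of them, and 0 had an unadjusted p below 0.05 in edgeR.

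**Figure D3:**
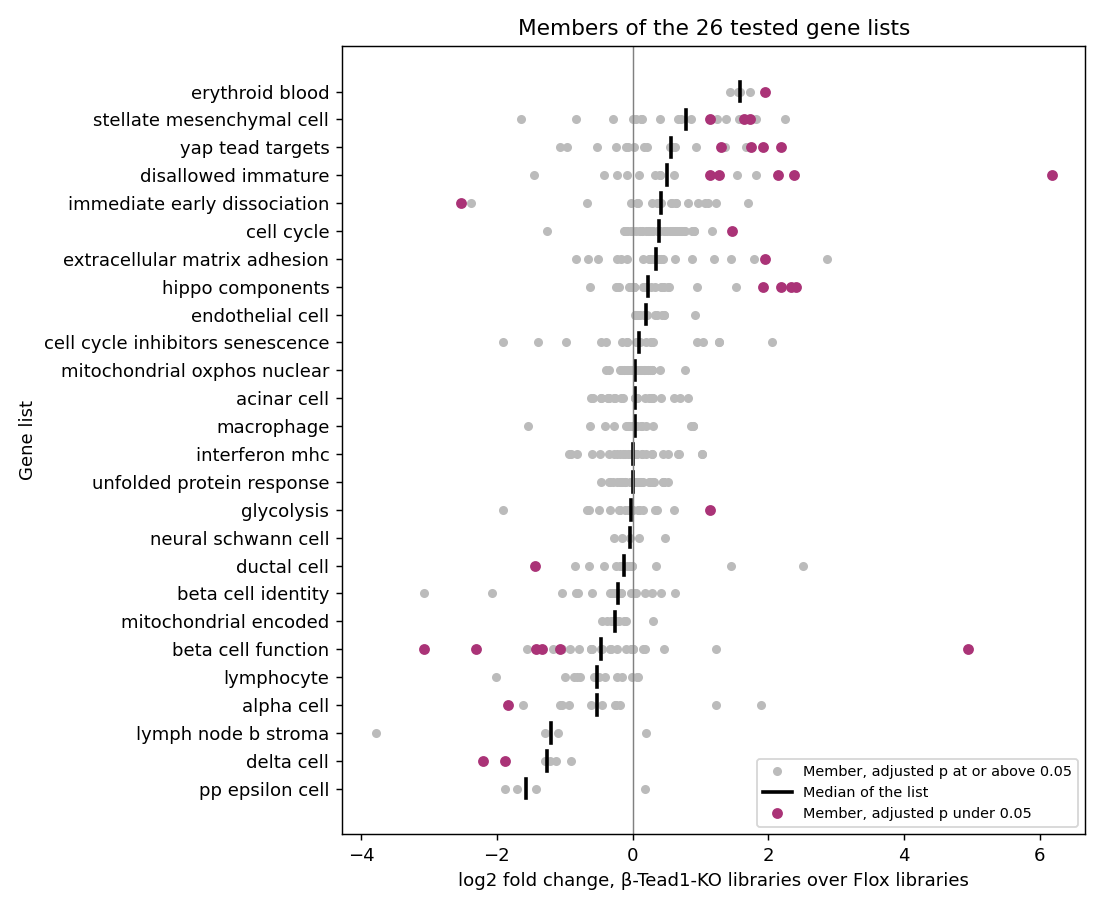
Log2 fold change of each tested member (points) of the 26 tested gene lists, with each list's median (black line); values to the right are higher in the libraries labelled β-Tead1-KO. Purple points are members with an edgeR adjusted p below 0.05: medians ran from -1.57 for the polypeptide and ε-cell list to 1.58 for the erythroid list, and the purple points of the disallowed and Hippo lists lie to the right of 0.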

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

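The tests on intron reads, on other splits of the libraries and on the junction share were chosen after the results were seen.

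Intron reads were not used in the comparison of genotypes. On these reads 108 genes passed the edgeR test, 62 higher and 46 lower in the libraries labelled β-Tead1-KO. Of the 504 genes called on exon reads, 439 were tested on intron reads, where 432 had the same direction and 79 were called again. Most of the 108 were thus genes already called on exon reads.

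Tead1 intron reads stood above both Flox libraries in both libraries labelled β-Tead1-KO. They were at 149 and 223 CPM of intron reads in Flox and at 431 and 900.3 CPM in β-Tead1-KO libraries 1 and 2. The log2 fold change of 1.84 (SE 0.60) did not pass over all genes (edgeR adjusted p = 0.318). Intron reads made up 13.2% and 37.7% of the reads of protein-coding genes in Flox libraries 1 and 2, and 14.8% and 30.8% in β-Tead1-KO libraries 1 and 2.

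Tead1 exon reads were not lower in the libraries labelled β-Tead1-KO, a total that cannot check the labels because it sums all exons and all cell types. For an exchange of 1 library of each genotype the other 2 splits of the 4 libraries were tested. They called 0 genes in edgeR (923 and 56 at an unadjusted p below 0.05) where the labelled split called 504 (2522). The labelled split was thus the largest difference between these libraries. Each other split holds that difference in its own spread between libraries, so its 0 calls cannot decide on such an exchange. A candidate explanation is that reads from Tead1 exons outside the deleted part keep the gene total up. The share of Tead1 exon reads crossing a junction was lower in both libraries labelled β-Tead1-KO. That fall lay at percentile 3.48 among 2788 genes that were not called and had at least 0.5 of the reads of the lowest Tead1 library. Junction reads themselves did not fall (log2 fold change 0.10), and Tead1 intron reads were higher without passing (1.84, SE 0.60). The lower share therefore cannot single out this explanation. An exchange of the labels of all 4 libraries cannot be told apart, since Tead1 would then have a log2 fold change of -0.41 and miss the threshold as well (edgeR adjusted p = 0.347). A response of Tead1 transcription to the genotype stays open as untested.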

How the results depend on the processing

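Unique exon reads, junction reads and intron share as a covariate were chosen after seeing the data; the other settings were not. The 504 changed genes became 1117 with the DESeq2 Wald test, 3595 with each lane as its own sample (which treats technical repeats as replicates), 1157 with the library number as a replicate block, 1189 with intron share as a covariate and 904 at an adjusted p under 0.10. Leaving out 1 library gave 67 to 2359. The other settings gave 393 (limma-voom) to 680 (unique exon reads), and in all these settings every one of the 504 genes that was tested kept its direction. Library numbers are shared between genotypes with no label that pairs them; the differences between library 1 and library 2 correlated at 0.39 between the genotypes across genes, which are not independent, so the replicate block is given here alone. Under it the lymphocyte list passed camera (adjusted p = 0.0150), as did Pdx1, Mafa, Ucn3, Glp1r, Pyy and Ppy in edgeR (adjusted p = 0.0132 to 0.0451). Leaving out either β-Tead1-KO library ended most calls of the 52 called genes named in the text, and leaving out either Flox library ended none. Without a β-Tead1-KO library the spread between libraries rests on the Flox pair alone. Without a Flox library it rests on the β-Tead1-KO pair alone. On junction reads 368 of 448 tested calls passed again. Of 492 calls tested on unique exon reads 485 passed again, with all 52 called genes named in the text among them.

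The Tead1 log2 fold change stayed positive in each setting run, from 0.10 on junction reads to 0.57 without β-Tead1-KO library 1, and passed the threshold with each lane as its own sample (0.41). Ins2 changed sign with no filter (0.018), on junction reads (0.023) and with a library left out (-0.11 to 0.089). Lane statistics at a mean count of at least 50 stayed on the same side. The pseudocount and filter planned for normalized values were not run, since counts were used, and edgeR's legacy mode does not enter camera.

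With an estimated correlation, where p rests on 2 residual degrees of freedom, 0 lists passed in place of 12. The other settings gave 9 to 16. Lists that missed the threshold and turned direction had these adjusted camera p: interferon and MHC 0.986 (limma-voom), 0.997 (lanes as samples), 0.956 and 0.882 (lane 1, lane 2) and 0.442 (junction reads); acinar 0.972 (DESeq2) and 0.912 (intron share); ductal 0.716 (junction reads); macrophage 0.957 (CPM of at least 1) and 0.941 (lane 1); neural 0.571 (no filter) and 0.771 (lane 2); immediate early 0.936 (DESeq2). With a library left out the ranges were 0.113 to 0.655 for the unfolded protein response, 0.0111 to 0.752 for oxidative phosphorylation, 0.282 to 0.959 for glycolysis, 0.493 to 0.960 for interferon and MHC, 1.53e-06 to 0.128 for acinar, 0.315 to 0.939 for macrophage, 8.25e-05 to 0.491 for lymphocyte, 1.17e-09 to 0.276 for immediate early and 0.00618 to 0.994 for mitochondrially encoded genes. The cause was not tested for these changes. Some of these lists then passed, as the low ends of the ranges show. With 2 libraries per genotype and these depths, 19.6% of 2-fold changes simulated at a common dispersion were recovered.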

Other observations

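The genes and tests of this part were chosen after the results were seen. Among the most abundant genes that changed at least 2-fold, Gpx3, a secreted glutathione peroxidase, went from 232 ± 55.7 CPM in Flox to 2041 ± 3.67 CPM in the libraries labelled β-Tead1-KO (SD, n = 2 each; log2 fold change 3.14, SE 0.29, edgeR adjusted p = 0.00813). The kinase Pak3 rose from 153 to 441 CPM (log2 fold change 1.53, SE 0.17) and the heparan sulfate proteoglycan Sdc4 from 97.2 to 377 CPM (1.96, SE 0.22). In the other direction the serine protease gene Prss53 went from 663 to 124 CPM (log2 fold change -2.41, SE 0.20; 51% unique reads), Phactr1 from 398 to 150.1 CPM on average (-1.41, SE 0.20) and Tmem215 from 275 to 68.5 CPM (-2.01, SE 0.17).

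Grouping the tested genes by the first 3 letters of their symbol gave 247 groups of at least 10 genes. No group passed after adjustment over the groups (Fisher's exact test, 1-sided, smallest adjusted p = 0.313). The 3 groups with the lowest unadjusted p in this exact test were genes starting with Ptp, 6 called of 39, 3 higher and 3 lower (p = 0.00177), Ald, 4 of 20, all higher (p = 0.00396), and Kcn, potassium channel genes, 7 of 63, 4 higher and 3 lower (p = 0.00502).

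Lower α-, δ- and polypeptide cell markers went with higher mesenchymal and erythroid markers in the libraries labelled β-Tead1-KO. A lower share of endocrine cells, taken alone, would raise the markers of every other cell type alike. The mean of the mesenchymal list minus that of the macrophage list was taken per library on the log2 CPM scale. It was 0.73 higher in the libraries labelled β-Tead1-KO (SE 0.12, 95% t interval 0.20 to 1.25, n = 2 per genotype), so these lists did not rise alike. A larger share of β-cells, taken alone, would lower the markers of all other types. The mean of the endothelial list was 0.28 higher (SE 0.041, 95% t interval 0.10 to 0.46), so this list did not fall. The camera call of that list was lost with an estimated correlation (adjusted p = 0.481), without Flox library 1 (0.0811) and without β-Tead1-KO library 2 (0.0510). The lists were picked after their medians had been seen, so the intervals do not decide on either explanation. Such shifts in cell shares, a change in the mesenchymal or blood cells alone, and changes of expression within the endocrine cells of this genotype stay open as untested.

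The higher Hippo and YAP/TEAD target lists in the same libraries may have more than 1 source. RNA from more mesenchymal cells cannot be told apart: relative to the mesenchymal list, the mean of the 43 tested members outside it differed by -0.29 between genotypes (SE 0.30, 95% t interval -1.60 to 1.02, n = 2 per genotype). Leaving out Flox library 2 cannot decide whether its low immediate early gene level is the whole source. In that fit the spread between libraries rests on the β-Tead1-KO pair alone, so a pass in it decides nothing. Without Flox library 2 the median of the immediate early list turned from 0.41 to -0.40, while that of the target list stayed positive. The target list passed camera all the same (adjusted p = 0.00117, median log2 fold change 0.46), with 5 members called in edgeR, all higher. Without Flox library 1 the target list missed the threshold (adjusted p = 0.0518), and with all 4 libraries and an estimated correlation the adjusted p was 0.421. A response of β-cells to the genotype stays open as untested.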
